A study of Arabidopsis thaliana with 11 samples.

How the data were processed

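Total RNA from dark-grown hypocotyls of Arabidopsis thaliana, accession Columbia, was measured on single-colour NimbleGen arrays of 1 high-density chip. A hypocotyl is the embryonic stem of the seedling. Per the labels' protocols, seeds stood for 3 days at 4 °C in the dark, received white light for 6 h at 20 °C and then grew in the dark for 4 days, so that hypocotyls were 96 h old. Each biological replicate was collected separately and pooled about 300 hypocotyls. The wild type has 6 replicates, numbered 1 to 6. The group labelled pme3 mutant, described in the labels as a loss-of-function line, has 5 replicates, numbered 1, 2, 3, 5 and 6. A labelled mutant replicate with number 4 is not analysed here.

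The deposited values are intensity on a linear scale, 1 per feature and array, summarised by the authors with RMA per the submitters' processing notes. RMA as generally run corrects background, makes the distributions of the arrays equal and summarises the probes of a feature. The version and the settings used are not given in the sources used here, nor are the genome build and annotation release behind the array. Each array holds 37118 features of 32627 loci; 26409 features rest on 4 probes, 10597 on 3, 53 on 2 and 59 on 1. A separate value table holds the same intensities, with a largest difference of 0 over all features and arrays. The median intensity per array lay between 3775.6 and 3909.2, so the arrays were already on a common scale. A between-array normalization of this kind removes any change in total RNA and measures each gene relative to the others. The files used here hold no detection calls, and features near the bottom of the scale have compressed fold changes. The number of arrays limits the precision.

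Feature names carry the locus, and symbols were taken from a RefSeq gene table of the TAIR10.1 assembly, in which 31993 of the loci were found. Loci without a symbol there keep their locus identifier. No coordinates are given, since the array's build is unknown, and neighbouring genes were taken from the order of locus numbers. Per-sample value columns of other samples numbered 0.

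Groups were taken from the labels. Intensities were log2-transformed and compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, all features, no filter, no covariate), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. A second count also asked for a fold of at least 1.5. Fold changes are labelled mutant minus wild type on the log2 scale, with the moderated standard error (SE). PME3 was in addition tested with an exact two-sided permutation test. For lists and neighbours, the feature with the highest mean stood for its gene.

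A total of 30 gene lists with 492 entries was fixed before the data were examined, together with the tests, the alternatives and the rule for naming genes. All entries were on the array. Family lists were not extended by product name, since the gene table holds no products. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 30 lists. camera compares a list with all other features; fry asks whether its members move, on balance, one way. PME3 belongs to no list. The genes named are PME3, the 12 largest rises and the 12 largest falls by fold change among genes past the threshold whose groups do not overlap, and per list up to 4 genes, the 2 risen and the 2 fallen genes of lowest p. A list with no gene past the threshold would have had its gene of lowest p named as values only. In the root and root hair list, 1 gene that this rule would name is not used here. Next to PME3, up to 4 genes past the threshold were named. Any other gene named was chosen after its values were seen, and the text says so.

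On simulated arrays with the means and residual spreads of the real features and 200 changed features of 37118, the same fit recovered 42% of changes of 1.25-fold, 78% of 1.5-fold, 98% of 2-fold and 100% of 4-fold, with 10 false calls. In a second simulation, camera called the 1 list that had been moved and 0 of 29 lists that had not. The simulated features were drawn independently of each other, whereas the real seed storage list had an estimated correlation of 0.48. The simulation therefore does not show how camera behaves on correlated lists.

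Alternatives were a second quantile normalization, centring on the median or on the 75th percentile, filters on dim features, averaged features of a gene, other variance models, array weights, the replicate number as a block or covariate, Welch's test per feature as an alternative only, stricter thresholds, and leaving out each array. Averaging arrays whose numbers lie 3 apart, using such arrays as a random block, leaving out chromosomes 1 and 4, and leaving out the root hair gene RHS12 from the pectin methylesterases were added after seeing the data. The standard-error column of the files was not used, because its scale is not stated. The names of the deposited arrays give odd chip positions for the wild type and even ones for the labelled mutant, so a side effect of position and the genotype cannot be told apart.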

Results

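Transcript levels were measured in etiolated hypocotyls of wild-type Arabidopsis (n = 6 arrays) and of hypocotyls labelled pme3 mutant (n = 5 arrays). PME3 encodes a pectin methylesterase, an enzyme that removes methyl groups from the pectin of the cell wall. The comparison asks which transcripts differ between hypocotyls with and without a working PME3 gene. Signal ran from 95.7 to 53727 over the arrays. Arrays of the same group correlated at 0.985 to 0.998 over all features, and arrays of different groups at 0.966 to 0.982. The first principal component held 65% of the variance and separated the groups; the second held 12.5% and separated wild-type replicates 2 and 5 from 3 and 6.

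The PME3 feature (AT3G14310_1, 4 probes) was higher, not lower, on the arrays labelled mutant. Its mean log2 intensity was 14.41 ± 0.02 there (SD, n = 5) and 13.81 ± 0.06 in wild type (SD, n = 6). The log2 fold change was 0.61 ± 0.040 (SE), or 1.52-fold, with a limma adjusted p of 4.91e-07, and each of the 5 arrays lay above each of the 6 wild-type arrays. An exact permutation test over all splits of the arrays into groups of 6 and 5 gave a two-sided p of 0.00216, the smallest it can give. This goes against the loss-of-function label as far as the probes report it. The insertion site and the positions of the probes are not given in the sources used here, and a probe outside the disrupted part checks nothing. The arrays are therefore called "labelled mutant" throughout, and every direction below rests on that label.

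**Figure D1:**
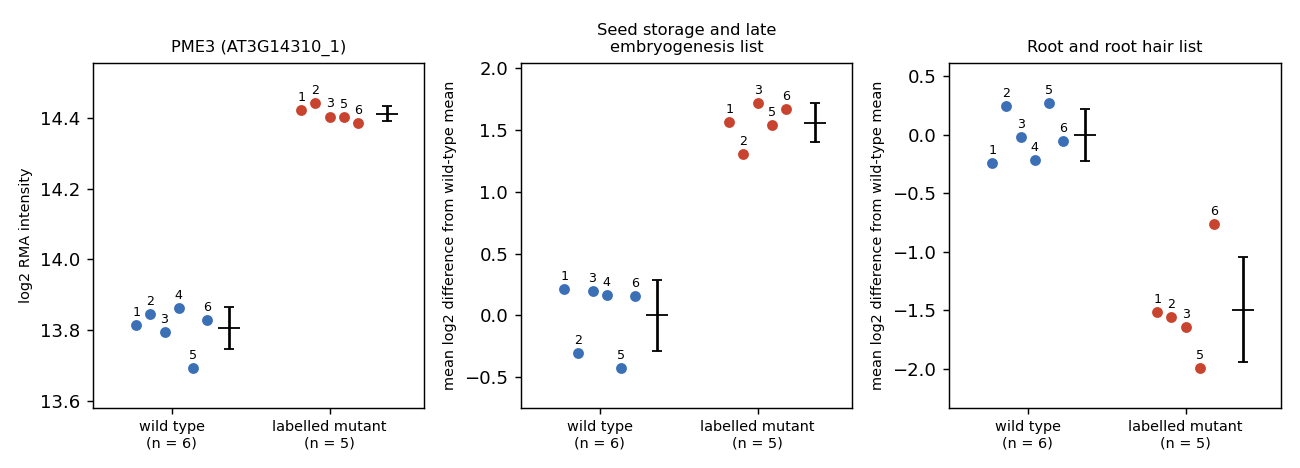
Values per array of PME3 (log2 RMA intensity) and of 2 gene lists (mean log2 difference from the wild-type mean over the members), for wild type (blue) and arrays labelled pme3 mutant (red); numbers are replicate numbers, and bars give the mean ± SD. PME3 lay between 14.39 and 14.44 on arrays labelled mutant and between 13.69 and 13.86 in wild type, and both lists separated the groups too.

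On arrays labelled mutant, transcripts known from maturing and dry seeds were higher, while root hair transcripts and many neighbouring loci on chromosomes 1 and 4 were lower. Past an adjusted p of 0.05, 6989 features (6683 loci) were higher and 5044 (4675 loci) lower, 32.4% of all features. With a fold of at least 1.5 these became 1264 higher and 1858 lower, and with a fold of at least 4, 94 higher and 281 lower. Most of the higher calls were thus small, and 2280 of them lay in the 25% of features with the lowest mean signal. Higher features made up 58.1% of the calls, and between 54.5% and 62.8% with median centring, 75th percentile centring or a second quantile normalization. All of these bring the arrays to a common centre, so the balance of higher and lower calls holds only relative to that centre. With arrays 3 numbers apart averaged, an alternative chosen after seeing the data, 3938 features were higher and 3236 lower.

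The largest rise was that of GASA2 (AT4G09610), a member of the gibberellin-regulated GASA peptide family, from 8.56 ± 0.35 to 12.51 ± 0.35 (log2 mean ± SD), a log2 fold change of 3.96 ± 0.19 with an adjusted p of 3.85e-08. GASA3, which belongs to the same family, rose by 2.99 ± 0.18. The embryogenesis protein gene ATECP31 rose by 3.39 ± 0.26 and the caleosin gene ATS1, whose product sits on seed oil bodies, by 3.00 ± 0.18. MEE8 rose by 3.36 ± 0.18. The remaining 7 of the 12 largest rises carry only a locus identifier: AT4G22485 (3.42), AT4G18690 (3.3), AT1G63190 (3.04), AT5G45690 (3.02), AT5G18450 (3.01), AT1G52560 (3.00) and AT3G58450 (2.99, log2 fold changes). GASA2 and GASA3 (AT4G09600) have adjacent locus numbers, not far past a run of lost signals described below, from AT4G09200 to AT4G09313. MEE8 (AT1G25310) likewise follows the run from AT1G24792 to AT1G25211. Other large rises, such as AT5G45690 and AT3G58450, lie on other chromosomes. A part of the line's background in these rises was not tested.

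Seed storage and late embryogenesis genes rose together: 20 of 23 members rose and 0 fell (21 and 0 adjusted over the list alone), with a median log2 fold change of 1.4. camera gave an adjusted p of 2.82e-12, fry 4.84e-05, and camera an adjusted p of 0.461 with an estimated correlation. GEA6, a late embryogenesis abundant protein gene, went from 10.88 ± 0.32 to 13.36 ± 0.18 (2.48 ± 0.15, adjusted p 1.99e-07), and M10 rose by 1.87 ± 0.11. Chosen after their values were seen, the cruciferin gene CRU2 rose by 2.06 ± 0.24 and the oleosin gene OLEO2 by 2.29 ± 0.24, while the cruciferin gene CRA1 (0.32 ± 0.12, adjusted p 0.0652) did not pass. The list mean, relative to the wild-type mean, was -0.31 and -0.42 in wild type 2 and 5, 0.16 to 0.21 in the other 4, and 1.3 to 1.7 on arrays labelled mutant. Of 9 markers of seed coat and endosperm, 3 rose and 1 fell beside them, with a median of 0.14 (camera adjusted p = 0.581, fry adjusted p = 0.0339). BAN (0.32) and MAN7 (0.25) rose and AT4G28370 (-0.26) fell.

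Among the listed genes of reserve lipid mobilisation and of vacuolar and storage-protein proteases, 1 rose. Of 19 reserve lipid mobilisation genes 0 rose and 2 fell, namely MFP2 (-0.22 ± 0.048) and AIM1 (-0.17 ± 0.051), both enzymes of fatty acid β-oxidation (camera adjusted p = 0.0700). Between 2 and 5 fell without 1 array in turn. Among 18 vacuolar and storage-protein proteases 8 fell and 1 rose (camera adjusted p = 0.0128, and adjusted p = 0.461 with an estimated correlation). ALPHA-VPE, a vacuolar processing enzyme, went from 12.47 ± 0.07 to 11.04 ± 0.34 (-1.43 ± 0.13), AT4G04460 fell by 0.60 on the log2 scale, and BETA-VPE, the form known from seeds, rose by 0.39 ± 0.082. Of the 4 subtilases, SBT3.5 fell (-0.21) and S1P rose (0.15); the S1P call was lost in 9 of 11 fits that left out 1 array. With arrays 3 numbers apart averaged, an alternative chosen after seeing the data because such wild-type arrays resembled each other, 1 lipid gene, 5 proteases and 0 subtilases fell.

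Root and root hair markers fell. Of 14 members 9 fell and 2 rose, with a median log2 fold change of -2.02 (camera adjusted p = 0.000549, adjusted p = 0.461 with an estimated correlation). The root hair regulator RSL4 went from 11.41 ± 0.55 to 9.15 ± 0.27 (-2.25 ± 0.24, adjusted p 3.35e-05) and the nitrate transporter gene NRT2:1 changed by -1.34 ± 0.12. The endodermal gene CASP1 rose by 0.18 ± 0.044. Within the list, 7 of the 8 root hair genes fell. The list mean was -0.76 on labelled mutant 6 and -1.51 to -1.99 on the other 4, relative to the wild-type mean. Of 28 markers of cotyledons and green tissue 2 rose, RBCS1B (0.44) and LHCB4.1 (0.20), 0 fell, and the median was 0.01. Adjusted over that list alone, 0 of the 28 passed, and the calls of RBCS1B and LHCB4.1 were lost in 9 and 8 of the 11 fits that left out 1 array.

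Cell wall families were split between rises and falls. Of 39 pectin methylesterases other than PME3, 10 rose and 6 fell, with a median of 0.04 and a mean of -0.19, which differ in sign (camera adjusted p = 0.997). AT5G04960 (-3.56 ± 0.34, adjusted p 1.36e-05) and RHS12, named for its root hair expression (-3.35 ± 0.24), fell most, against rises of PMEPCRF (0.33 ± 0.054) and AT5G07410 (0.38 ± 0.096). Without 1 array in turn, 6 to 10 rose and 5 to 7 fell, and with arrays 3 numbers apart averaged 5 rose and 3 fell. Pectin methylesterase inhibitors split 3 up and 3 down of 10: AT2G47670 (0.73) and AT5G62360 (0.71) rose, AT1G62760 (-1.63) and AT1G62770 (-0.44) fell. Of 23 polygalacturonases, pectate lyases and pectin acetylesterases 5 rose, AT5G63180 (0.47) and AT3G09410 (0.24) at the lowest p, and 4 fell. The polygalacturonase gene ADPG1 went from 12.62 ± 0.04 to 10.18 ± 0.49 (-2.44 ± 0.18), and PGAZAT fell by 0.54 on the log2 scale. Of 6 pectin synthesis genes only TSD2 passed (-0.16), and 0 did with arrays 3 numbers apart averaged, when 2 polygalacturonase and related genes fell.

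Among 19 expansins, which loosen the wall, 2 rose, EXPA15 (0.15) and EXPA6 (0.29), and 6 fell, with EXLB1 (-0.97 ± 0.13) and EXPA14 (-0.51 ± 0.055) at the lowest p. Of 21 xyloglucan endotransglucosylase/hydrolases 4 rose and 6 fell. XTH25 went from 11.24 ± 0.47 to 13.64 ± 0.19 (2.40 ± 0.20) and XTH20 rose by 0.96 ± 0.14, whereas XTR6 (-0.70 ± 0.069) and EXGT-A3 (-0.22) fell. Of 10 primary wall cellulose synthesis genes CSI1 rose (0.12) and CESA2 (-0.32) and CESA9 (-0.35) fell. Of 18 secondary wall and xylem genes 5 rose, among them MYB46 (0.39) and NAC012 (0.32), and FRA8 fell (-0.35). Of 9 structural wall glycoproteins HRGP1 fell (-0.72). Of 9 class III peroxidases Prx37 (1.03 ± 0.13) and AT5G64120 (0.26) rose and PRX52 fell (-0.39). None of these wall lists passed camera, while expansins (adjusted p = 0.0324) and pectin methylesterase inhibitors (0.0311) passed fry, both towards lower values. Of the 11 fits without 1 array, the call of AT5G64120 was lost in 8, CSI1 in 7, FRA8 in 6 and PRX52 in 2. Without 1 array in turn, 4 to 6 expansins fell and 2 to 4 xyloglucan enzymes and 2 to 5 secondary wall genes rose. With arrays 3 numbers apart averaged, 0 expansins rose and 3 fell, 3 xyloglucan enzymes rose and 4 fell, and 2 secondary wall genes rose.

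More defence and jasmonate genes rose than fell. In the defence and damage list 10 of 23 rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.0233, adjusted p = 0.461 with an estimated correlation, and 0.0544 by the first test without labelled mutant replicate 6). The transcription factor gene WRKY53 rose by 0.78 ± 0.086 and the defensin gene PDF1.2 by 0.83 ± 0.11; the chitinase gene HCHIB (-0.55) and the pathogenesis-related gene PR4 (-0.62) fell. In the jasmonate list 8 of 19 rose and 1 fell (camera adjusted p = 0.0128, adjusted p = 0.461 with an estimated correlation). The signalling repressor gene JAZ10 rose by 0.74 ± 0.061 and the biosynthesis gene AOC3 by 0.48 ± 0.061, and VSP1 fell (-0.44), a call lost in 5 of the fits without 1 array. Hypoxia genes went the other way, with 6 of 12 lower and 1 higher (camera adjusted p = 0.0128, adjusted p = 0.461 with an estimated correlation). ERF71 changed by -1.01 ± 0.10 and AT4G33070 by -0.78 ± 0.098, while ERF73 rose by 0.26 ± 0.051. With the dimmest 50% of features left out, the calls of the defence, hypoxia, protease and root lists ended.

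The remaining lists did not pass camera. Brassinosteroid genes had 9 of 16 higher and 0 lower (adjusted p = 0.0505), with ROT3 (0.31) and RLP44 (0.34) at the lowest p. Light signalling and flavonoid synthesis genes also had 9 of 14 higher and 0 lower (adjusted p = 0.0505), among them the flavonoid enzyme genes TT4 (0.57 ± 0.096) and TT5 (0.37 ± 0.083). Both counts moved with the choice of arrays: with arrays 3 numbers apart averaged, 4 brassinosteroid genes and 1 light and flavonoid gene rose, and without 1 array in turn 7 to 9 and 5 to 9. The lists passed camera in 2 and 4 of the 11 fits without 1 array, and both passed fry (adjusted p = 0.0101 and 9.10e-04). Of 15 clock genes 3 rose, including LHY (0.78 ± 0.11) and AT4G33980 (0.76), and 5 fell, including PRR5 (-1.35 ± 0.14) and GI (-0.75 ± 0.12). After the same averaging 1 clock gene rose and 4 fell. Of 24 glucosinolate genes 7 rose, with MYB51 (0.52) and UGT74B1 (0.33), and 7 fell, with IMS2 (-1.40 ± 0.11) and TGG2 (-1.04). Among heat shock genes 5 of 11 rose, including HSP17.6A (1.76 ± 0.28) and HSP23.6-MITO (1.43 ± 0.26), and HSFA2 fell (-0.80), a call that ended with the same averaging. The heat shock list mean, relative to the wild-type mean, was -0.42 and -0.52 in wild type 2 and 5, 0.19 to 0.31 in the other 4, and 0.30 to 0.73 on arrays labelled mutant. Of 9 genes of touch, cold and handling STZ (0.65) and WRKY40 (0.99) rose and 4 fell, with DREB1A (-1.70 ± 0.20) and CBF2 (-1.13 ± 0.15) at the lowest p.

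Of 32 auxin genes 6 rose, with GH3.3 (0.27) and IAA1 (0.39), and IAA6 (-0.60) and IAA19 (-0.22) fell. Of 12 gibberellin genes GAI (0.34) and RGA1 (0.13) rose and GASA1 (-0.20) and ATGA2OX1 (-1.69) fell; the RGA1 call was lost in 3 of the fits without 1 array. Of 14 ethylene genes 4 rose, with ACS6 (0.53) and ACS8 (0.97). Of 12 abscisic acid and dehydration genes 4 rose, with HAI2 (0.56) and RAB18 (0.94), and the list passed fry (adjusted p = 4.00e-04). Without 1 array in turn, 3 to 7 auxin and 2 to 4 ethylene genes rose, and with arrays 3 numbers apart averaged 3 auxin genes, 1 ethylene gene and 1 gibberellin gene did. Of 118 named values, 21 lost their call after that averaging, with fewer arrays: AIM1, S1P, SBT3.5, TSD2, EXPA15, EXPA6, CSI1, FRA8, AT5G64120, VSP1, IAA19, RGA1, ATGA2OX1, ACS8, HSFA2, AT4G33980, TT5, RBCS1B, CASP1, AT3G14360 and AT3G14320. Their fold changes stayed similar, such as -1.70 for ATGA2OX1 and 0.97 for ACS8 after averaging. By fry, which asks for a shift within the list alone, 13 of the 30 lists passed; by camera at the preset correlation 6 did, and 0 with an estimated correlation.

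**Figure D2:**
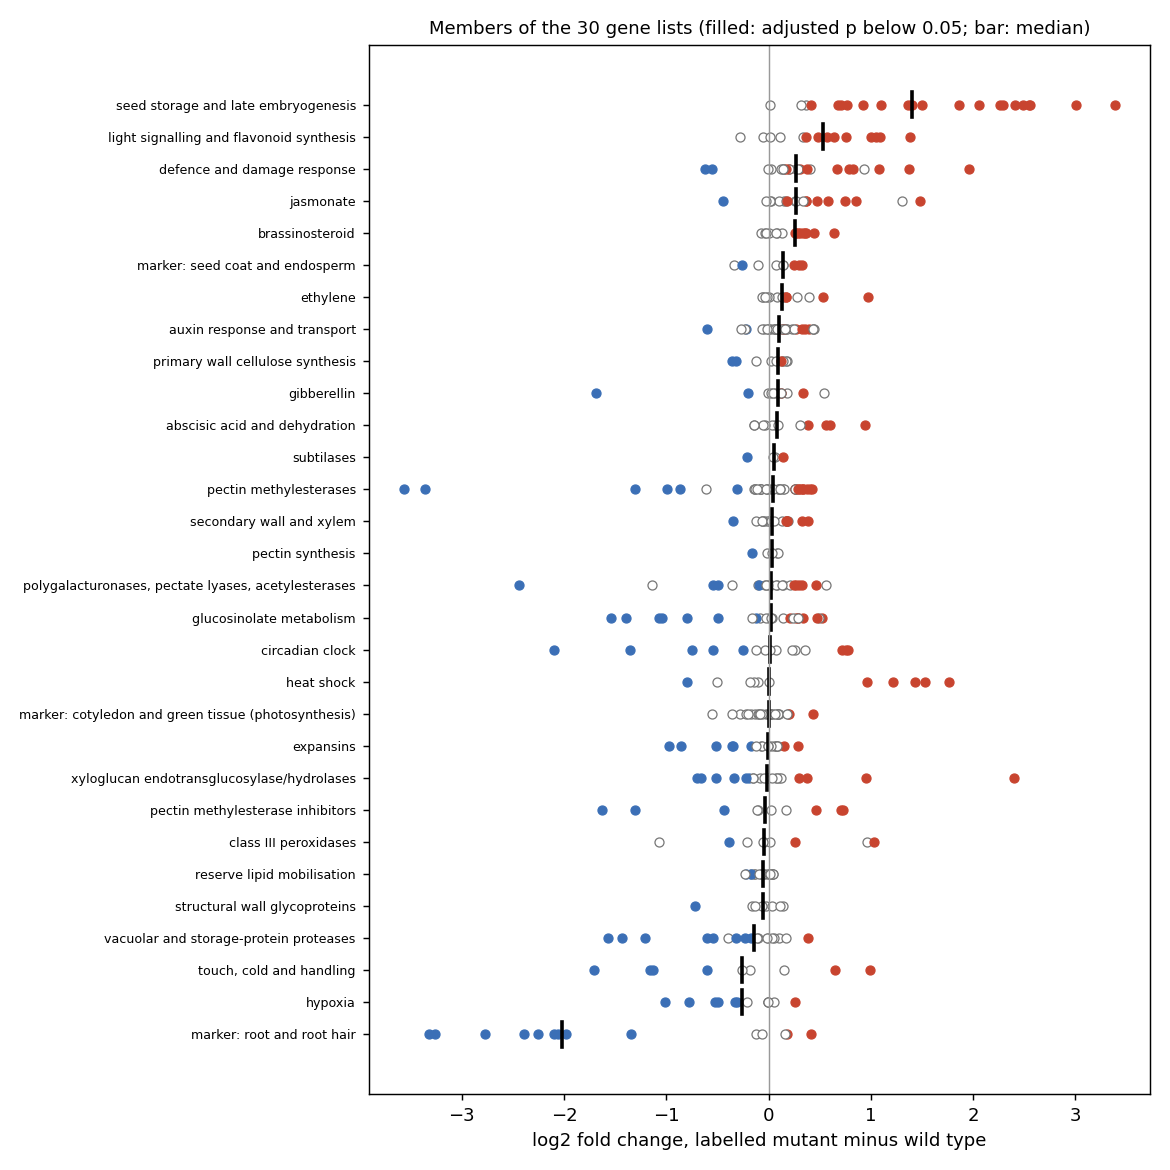
Log2 fold change (labelled mutant minus wild type) of each member of the 30 gene lists, ordered by median; filled points passed an adjusted p of 0.05 (red higher, blue lower), open points did not, and bars mark the medians. The seed storage and late embryogenesis list has the highest median (1.4) and the root and root hair list the lowest (-2.02).

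The 12 largest falls took signal into the dimmest 25% of features. AT1G58150 went from 12.53 ± 0.12 to 7.04 ± 0.23 (-5.49 ± 0.099, adjusted p 1.57e-11), and AT4G14905 from 12.82 ± 0.10 to 7.38 ± 0.66. The others were AT4G09250 (-5.37), AT4G09200 (-5.26), AT1G27180 (-5.23), AT1G58400 (-5.10), AT1G24825 (-5.0), the pseudogene AT1G58889 (-4.87), AT4G36140 (-4.85), AT4G19500 (-4.85), AT2G41440 (-4.84) and VPS54. For VPS54, 1 feature changed by -5.32 and another of the same gene by -0.88. All 12 had a mean below 9.18 on arrays labelled mutant, the upper bound of that range, but some varied widely there, such as AT4G19500 (8.77 ± 1.16) and AT4G09200 (8.07 ± 1.19). Probe sequences are not given in the sources used here, so signal shared between gene copies was not checked.

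Altogether 163 loci had a feature that fell at least 4-fold into the dimmest 25% of features without overlap between the groups. In the other direction, 36 loci had one that rose at least 4-fold from it. Root hair genes made up 6 of the 163 loci, RSL4 and RHS12 among them. Of 31 lost-signal loci with several features, 14 had another feature that fell less than 2-fold. For AT1G51270 (7.08 and 7.99), AT1G58280 (6.71) and IRT2 (7.56, wild-type mean log2), such features were already dim in wild type. They had little room to fall and say little about the transcript. For CAT2, 1 feature changed by -3.24 and another by -0.19, so a lost feature is not always a lost transcript. Of the 163, 86 lie on chromosome 1 and 41 on chromosome 4, against 13, 9 and 14 on chromosomes 2, 3 and 5. The largest run, from AT1G24792 to AT1G25211, held 12 such loci among 21 neighbours, and that from AT4G09200 to AT4G09313 held 8 among 11.

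**Figure D3:**
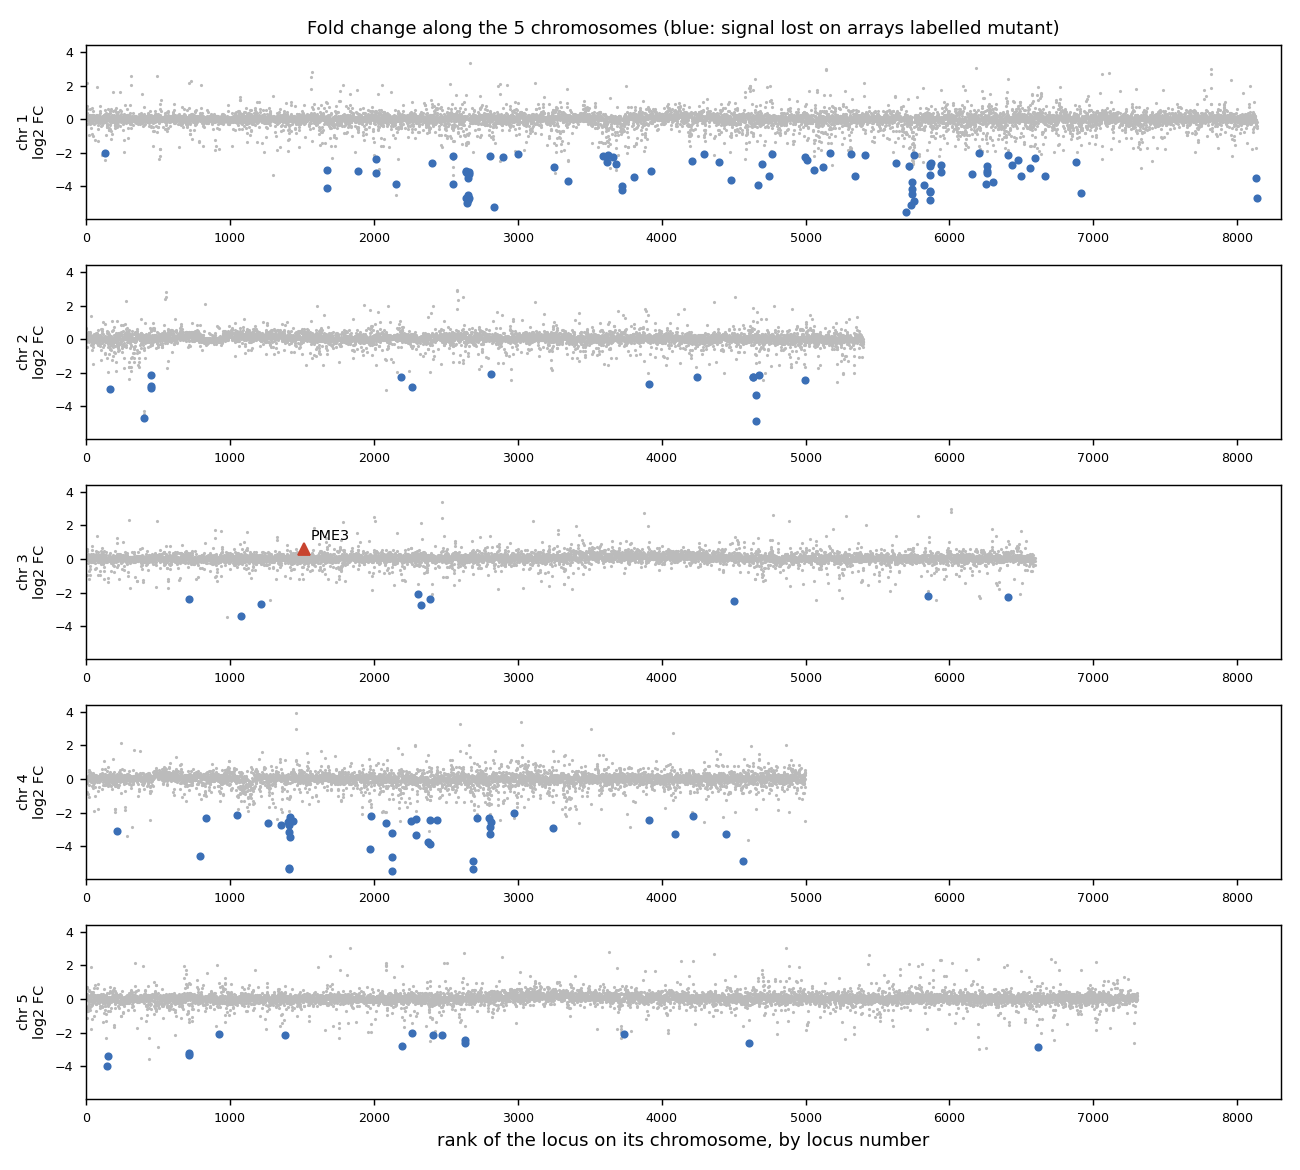
Log2 fold change (labelled mutant minus wild type) of each feature against the rank of its locus on chromosomes 1 to 5; blue points are features that fell at least 4-fold into the dimmest 25%, grey points all others, and the triangle is PME3. Lost signals crowd on chromosomes 1 (86 loci) and 4 (41 loci).

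Genes next to PME3 changed no more often than others. Of 28 genes from AT3G14200 to AT3G14420, 9 passed the threshold (5 higher, 4 lower), or 32.1%, against 32.5% of all other genes (two-sided Fisher's exact p = 1). Those of lowest p were AT3G14260 (-1.18 ± 0.16), AT3G14395 (0.44 ± 0.077), AT3G14360 (-0.31) and AT3G14320 (0.26).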

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

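The tests of single mislabelled arrays, of exchanged labels, of paralogs, of runs of neighbouring loci, of the distance to PME3 and of random genes beside the root hair genes were chosen only after the results were seen. Of 300 groups of arrays examined for an array far from the others, 5 held one, and chance gives about 15. The stray values were 13.75 for AT3G09410 in wild type 1 (others 13.63 to 13.66), 11.18 for EXLB1 in labelled mutant 3 (others 11.74 to 11.84), 13.90 for XTR6 in wild type 2 (others 14.14 to 14.28) and 7.92 for BAN in wild type 1 (others 7.78 to 7.81), all log2 intensity. The auxin list had a mean of 0.21 in labelled mutant 6, relative to the wild-type mean, against 0.06 to 0.09 in the other arrays labelled mutant.

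PME3 signal was higher on arrays labelled mutant. Single wrong labels are argued against, since 0 of the 11 arrays correlated best with an array of the other group. Signal from a paralog cannot be told apart from PME3 signal: the largest log2 fold change among the other listed pectin methylesterases was 0.43 (PME38, 95% interval 0.18 to 0.67), which overlaps that of PME3 (0.52 to 0.69), and probe sequences are not given. A full exchange of the group labels cannot be told apart from correct labels either, since the lost signals (163 loci on arrays labelled mutant, 36 the other way) decide only if the accession behind the array design is known. A transcript from the insertion allele may also reach the 1 PME3 feature, which the probe positions and insertion site would decide, so the genotype effect itself stays open.

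Signal was lost in runs of neighbouring loci. With copies of like signal counted once, 29.7% of 145 such loci had another within 5 neighbours, against a median of 4.14% and a highest value of 14.5% in 10000 random draws. That share describes the runs and supports no cause. Pseudogenes made up 23.3% of the 163 loci, 14.7% of other loci and 2.15% of 93 loci with other falls of at least 4-fold. Among loci with several features, 14 of 31 with lost signal had another feature that fell less than 2-fold, against 4 of 12 with other falls. Both comparisons were made after the results were seen, and neither forbids lower expression. Differences in sequence or gene copies between the line's background and the probes therefore cannot be told apart from lower expression without the sequence of the line. Variation carried along with the PME3 locus is argued against, as 0% of the 163 loci lay within 200 loci of PME3. An effect of the mutation on these loci stays open, because background and genotype coincide in these groups.

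Root hair genes were lower on arrays labelled mutant: 23 of 26, with a median of -2.19. Less root tissue in the harvest was examined with 20 root genes outside the hair gene sets. Their median was -0.19 (95% bootstrap interval -0.41 to 0.01), above 25% of the hair genes' median fall (-0.55). This does not decide it, because bright members such as ESB1 and CASP5 (both 14.46 in wild type, log2) may be expressed in the hypocotyl itself. Such genes would hold the median up whatever the amount of root. Of the 20, 4 fell, WOX5 (-0.85) among them, and 1 rose. Other dim genes of the set were lower without passing: NAC070 (-0.61), NAC015 (-0.51), PLT2 (-0.47), SMB (-0.36) and PLT1 (-0.28), against FEZ (0.07). Fold changes are compressed at such signal, so a larger loss of the tissue expressing these dim genes is not excluded. Nor is a loss of root tissue as a whole. Sequence differences against the probes are argued against as the whole cause: 21 of the 26 fell at least 2-fold, against at most 7 in random draws of genes of like signal, and 7 of the 8 hair genes on the list fixed beforehand, against at most 5. A first test, for lost loci within 5 neighbours of the fallen hair genes, gave a share equal to the 95th percentile of its random draws (13%) and did not decide, and sequence differences at single hair genes stay open. An effect of the genotype on root hairs at the hypocotyl base was not tested and stays open.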

How the results depend on the processing

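PME3 kept its direction and its side of the threshold under every alternative run, with a log2 fold change of 0.58 to 0.62 without 1 wild-type array or 1 labelled mutant array in turn. The counts of 6989 higher and 5044 lower features moved by over 1.5 times with the dimmest 50% of features left out (3067 and 2613), a fold of at least 1.5 (1264 and 1858), an adjusted p under 0.01 (3302 and 3179) and treat against 1.2-fold (1036 and 1702); these test fewer features or ask for more by construction. Among the alternatives chosen after seeing the data, they moved to 3938 and 3236 with arrays 3 numbers apart averaged, which leaves 6 arrays, and to 4215 and 2233 without chromosomes 1 and 4. Of the 7174 features called after averaging, 6984 were called in the main comparison too. Without single arrays the counts ran from 5124 to 7086 higher and from 4225 to 5010 lower. Replicate numbers were not used as pairs: deviations of same-numbered arrays correlated at 0.29, -0.06, 0.10, -0.03 and 0.05 for numbers 1, 2, 3, 5 and 6, and the fixed replicate block gave 5505 higher and 4226 lower features, with 12 of 118 named values losing their call, HSFA2 and TSD2 among them. Of the same 118, 51 lost it with treat against 1.2-fold, which asks for more, and 11 with Welch's test.

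The number of lists past the threshold went from 6 to 0 with an estimated correlation, to 13 with fry, which asks another question, and to 3 with the dimmest 50% of features left out, and ran from 5 to 9 without single arrays; the cause was not tested. Changed genes next to PME3 numbered 22 of 77 (28.6%) in the wider window, against 9 of 28 (32.1%) in the main one. Among the brighter 50% of features they numbered 4. Named genes gave 3079 values on the same side of the threshold, 170 of the same direction that fell short and 0 reversed, and lists 506, 11 and 0, with 23 newly past it. Without RHS12, 10 of the 38 other pectin methylesterases were higher and 5 lower. Dim features limit all counts: in the dimmest 25% the median log2 fold change was 0.09, against 0.02 in the brightest 25%.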

Other observations

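The tests of arrays 3 numbers apart were chosen only after the result was seen, as were all genes and chromosome blocks named in this part. No list of iron genes was tested; the 8 genes named next, known from iron uptake, were picked because they were lower on arrays labelled mutant. The iron transporter gene IRT1 changed by -2.06 ± 0.31 on the log2 scale, its relative IRT2 by -2.31 ± 0.27 and the ferric reductase gene FRO2 by -1.22 ± 0.18. A dimmer feature of IRT2 changed by -0.34. The regulators bHLH38 (-2.18 ± 0.30), BHLH100 (-2.23 ± 0.25) and FRU (-0.98 ± 0.14) fell too, as did NAS1 (-2.29 ± 0.18), which makes the metal chelator nicotianamine, and CYP82C4 (-3.24 ± 0.23). IRT2, bHLH38, BHLH100 and CYP82C4 are also among the 163 loci with lost signal. All 8 iron genes passed the threshold without overlap between the groups. Root hair genes moved with them (23 of 26 lower, median -2.19), as did the nitrate transporter gene NRT2:1 (-1.34), and IRT1 is itself a member of the root and root hair list.

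Falls of at least 1.5-fold came in blocks along the chromosomes. They made up 8.16% of the features on chromosome 1 and 7.14% on chromosome 4, against 3.72%, 2.69% and 3.11% on chromosomes 2, 3 and 5. By blocks of 500 loci the share reached 15.2% on chromosome 1 and 13.7% on chromosome 4. The first block of chromosome 2 had 8.33% and the second 0.57%. Rises of the same size were more even, at 3.90%, 2.98%, 2.69%, 3.92% and 3.53% on chromosomes 1 to 5. The flowering repressor gene FLC changed by 0.87 ± 0.28 on the log2 scale (limma adjusted p 0.0316), with overlapping groups. The phytochrome gene PHYD (AT4G16250) changed by -0.68 ± 0.051 (limma adjusted p 1.53e-06) without overlap. PHYD is thus itself among the falls of at least 1.5-fold on chromosome 4.

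Wild-type arrays whose numbers lie 3 apart resembled each other. Deviations from the group mean correlated at 0.18 for replicates 1 and 4, 0.58 for 2 and 5, and 0.69 for 3 and 6, and at 0.07 and 0.03 for labelled mutant pairs 2 and 5, and 3 and 6. Unrelated arrays would give about -0.20 in the wild type and -0.25 in the labelled mutant. The wild-type mean of 0.48 ranked 1 among the 15 ways to pair the 6 wild-type arrays, the next being 0.17, and that of the labelled mutant pairs (0.05) ranked 2 among 15 ways, the highest being 0.11. A shared batch may lie behind it, but 15 pairings cannot give a share under 0.05, and the labels call each replicate separate. Heat shock genes were lower in wild type 2 and 5 (-0.42 and -0.52 relative to the group mean) than in the other 4 (0.19 to 0.31), but higher in labelled mutant 2 and 5 (0.60 and 0.73 relative to the wild-type mean) than in 1, 3 and 6 (0.30 to 0.39). Class III peroxidases were lower in labelled mutant 2 and 5 (-0.26 in both) and higher in 3 and 6 (0.31 and 0.35). In wild type they went the other way, with 0.12 and 0.07 in 2 and 5 and -0.18 and -0.20 in 3 and 6. Markers of cotyledons and green tissue were higher in 2 and 5 than in 3 and 6 in both groups (wild type 0.25 and 0.36 against -0.29 and -0.32, labelled mutant 0.08 and 0.11 against -0.16 and -0.14).

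A random division of the arrays is argued against as the source of the changed features. The real grouping called 12033, and the highest of the other 99 splits drawn called 74, so 1 of 100 splits reached the real count. Each of the other splits mixed arrays of both groups. Any cause that parts the groups, chip position included, would therefore give such a result.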
